A study of Mus musculus with 4 samples.

How the data were processed

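RNA of adult mouse heart muscle cells was profiled on 4 Agilent 1-colour arrays, 2 from animals given PBS (control) and 2 from animals given doxycycline for 2 days, per the labels. The arrays were assigned to groups by the sample titles. They lay on 1 slide and were scanned on 1 day, so neither slide nor day could be set as a block. Control arrays held positions 1 and 2 on the slide and doxycycline arrays 3 and 4, so position cannot be told apart from treatment. The replicate number in the titles was not stated to mark a shared animal, litter or day.

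Per the file headers, the authors extracted spot intensity with Agilent Feature Extraction 10.7.1.1 from Cy3 scans. The deposited processed intensity is background-subtracted and corrected for spatial trend within each array, on a linear scale, and is not normalized between arrays. The deposited files also give the median intensity of each spot and of its local background, and other columns, flags for spots well above background, saturated or outlying, which are used here per the file headers. Any further processing by the authors is not given in the sources used here. Each array had 44397 spots, of which 43020 were not controls, for 39429 distinct probes; 399 probes were spotted 10 times. No spot was saturated.

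The files give an accession for each probe and no gene symbol, and their design build is mm9. Accessions were named, without versions, through a RefSeq gene table of assembly GRCm38.p6, which was used for names only, and no coordinates are given. In all, 27508 probes were named, for 20886 genes; 1641 probes had a RefSeq accession that did not match and 10280 had another identifier. Probes without a name were kept out of the main test and tested in an added alternative. Columns of other series in the files numbered 0.

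The processed intensity was log2-transformed, the 75th percentile of the non-control spots of the array was subtracted, spots flagged as outliers were left out and spots of a probe were averaged. A probe was kept if well above background on at least 2 of the 4 arrays, a probe with several spots being so if at least 0.5 of its spots were. There were 35 probes with every spot flagged on an array, which were left out. The brightest probe stood for a gene, which left 12542 genes. Where a gene was not well above background on any array of a group, its fold is given as a lower bound, the bright group's mean against the mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background, all on the normalized log2 scale. Array signal over background and the number of arrays set the precision.

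Differences were tested two-sided with limma 3.58.1 (lmFit and eBayes, trend and robust off) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. With 2 arrays against 2, a permutation test cannot give a p below 0.333, and the limma test takes its spread from all genes (4.69 prior and 2 residual degrees of freedom). In total, 32 gene lists were fixed, of which 31 had at least 3 genes tested; the list of introduced factors had fewer. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry. The steps were tested on simulated arrays with 200 changed genes of 12542 in 20 draws, which gave a mean of 4.95 false calls per draw, and 0.1 calls with no gene changed. A shift of 0.5 in the oxidative phosphorylation list was called in 19 of 20 draws. The simulated genes varied independently and with the same spread on every array. These figures therefore do not cover correlated genes or an array that deviates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

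The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 4 introduced factors, the highest and lowest genes that passed or, where none passed, the 6 with the smallest p in each direction, genes with a bound that passed (there were 0), and up to 4 members per list with the smallest p. Clone and predicted-gene names were passed over, and some items that the rule or a list takes in are not reported here. Of the list members so chosen, the text gives those needed to describe each list. Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on dim probes and a filter on all 4 arrays, the mean of a gene's probes, a variance trend, a robust variance, the replicate number as a block, each array left out in turn, and an unadjusted p under 0.05 with an absolute log2 difference of at least 1. Normexp was run on the median spot signal, since a mean signal was not used here. The choices that depended on the files' format (naming through accessions, the rule for repeated spots and the median signal for normexp) were made after the files were seen and before any fit. Array weights and the test of every accession were added after the data were seen. Intervals of list medians in the closing section come from 10000 bootstrap draws over genes. They do not cover the spread between arrays, and genes are not independent.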

Results

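Gene expression was measured in adult heart muscle cells isolated from 10-week-old male mice in which the reprogramming factors Pou5f1, Sox2, Klf4 and Myc can be switched on by doxycycline in cells that use the cardiac αMHC promoter. Mice were injected with doxycycline or with saline (PBS) for 2 days. RNA from each preparation was labelled with Cy3 and hybridised to a 1-colour Agilent mouse array, with 2 control and 2 doxycycline arrays on 1 slide scanned on 1 day. The 75th percentile of the processed signal was 112 and 171 on control arrays 1 and 2 and 248 and 193 on doxycycline arrays 1 and 2, and 50.6% to 51.8% of the spots were well above background. Repeated spots of a probe varied by a median of 10.99% on control array 1 and by 4.0% to 4.8% on the others, and spike-in spots by 18.3% on control array 1 and by 2.9% to 6.7% on the others. Control array 1 was outside the scanner software's accepted range on both measures. Levels below are log2 signals minus the 75th percentile of the array, and differences are doxycycline minus control with the standard error of the fit (SE, n = 2 per group). The number of arrays limits the precision. Nothing in the sample descriptions says that the arrays came from separate animals, so the tests measure the spread between these samples, which may be technical.

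The arrays address which transcripts differ in heart muscle cells after 2 days of factor induction. Every control animal received PBS and no array came from animals given doxycycline without the factors, so the comparison covers drug and factors together. Of the introduced factors, Myc was the one with a large difference. It read -2.34 and -3.21 on the control arrays and 1.77 and -0.49 on the doxycycline arrays, a difference of 3.42 ± 0.77 (SE) that did not pass the test over all genes (adjusted p = 0.331). Its processed signals were 22.2 and 18.5 against 844 and 138. Klf4 was well above background on every array and differed by -0.28 ± 0.48 (SE, adjusted p = 0.973). Sox2 was not well above background on any array, and Pou5f1 was so on doxycycline array 1 alone, with a processed signal of 15.8. Whether the probes detect the introduced copies is not known, because the probe sequences were not used here.

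The genes with the smallest p values were a mixed group with large differences, and none passed the test over all genes. Cdo1, which oxidises cysteine, read -2.51 and -2.87 on the control arrays and 0.69 and 1.04 on the doxycycline arrays, a difference of 3.56 ± 0.41 (SE, 11.8-fold). The metal-binding protein gene Mt2 differed by 5.24 ± 0.63 and Serpina3n, a secreted protease inhibitor of the acute phase, by 5.25 ± 0.66, all 3 with adjusted p = 0.149. Dynlrb2, a dynein light chain, was not well above background on either control array and was at least 4.78-fold higher after doxycycline, and Doc2b, a calcium sensor of vesicle fusion, was likewise at least 5.56-fold higher. In the other direction Apln, which encodes the peptide ligand apelin, read 0.60 and 0.04 on the control arrays and -3.71 and -4.15 on the doxycycline arrays, a difference of -4.25 ± 0.44 (adjusted p = 0.141), and 1 of the 2 doxycycline arrays was well above background. Dbh, the enzyme that makes noradrenaline, differed by -3.63 ± 0.51 (adjusted p = 0.165). Lrrc17 was at least 5.80-fold lower after doxycycline, the dendritic cell lectin gene Cd209a at least 3.49-fold lower, the transcription factor gene Arnt2 at least 2.26-fold lower and Slc35f1 at least 1.93-fold lower. These 4 were not well above background on either doxycycline array. A second Cd209a probe was below background on all arrays. A second Slc35f1 probe, well above background on 1 array alone, differed by -0.55.

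**Figure D1:**
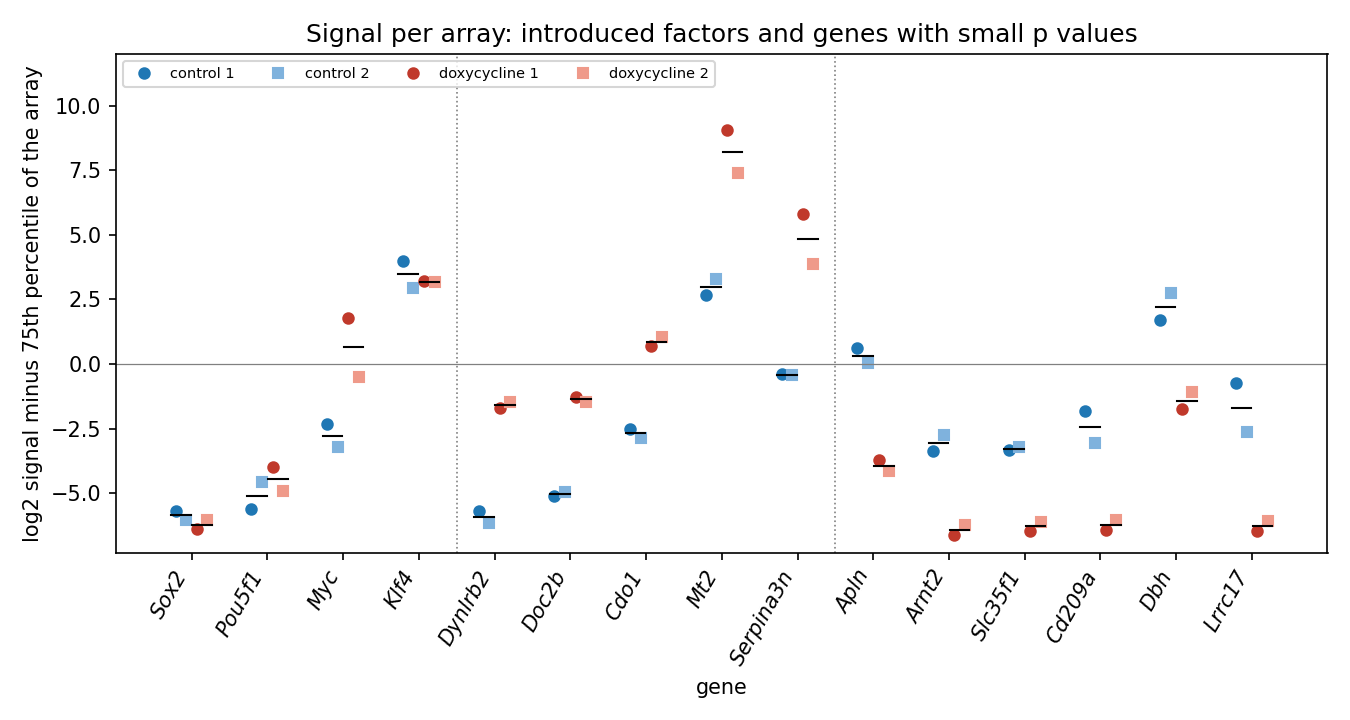
Log2 signal minus the 75th percentile of each array (y axis) for the 4 introduced factors, 5 genes with small p values above control and 6 below it (x axis, parted by dotted lines). Circles and squares are arrays 1 and 2 of control (blue) and doxycycline (red), and black bars are group means of 2 arrays. Cdo1 lies at -2.51 and -2.87 on the control arrays and at 0.69 and 1.04 on the doxycycline arrays, while the 2 doxycycline values of Myc, 1.77 and -0.49, lie far apart.

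Of 12542 genes tested with limma, 0 were higher and 0 lower after doxycycline at an adjusted p under 0.05, and the smallest adjusted p was 0.141. At an unadjusted p under 0.05 there were 886 genes, 398 higher and 488 lower, where 627 would be expected with no effect. The groups did not overlap for 35.3% of the genes, where chance gives 33.3%. In simulated data of this size the test found 4.25% of genes changed by a log2 difference of 2, 47.8% at 3 and 83.4% at 4. The simulation had independent genes and no deviating array. The count of 0 depended on how the arrays were scaled: scaling to the median gave 95 higher and 33 lower. It also depended on which arrays were used, since genes were called when either doxycycline array was left out. In those fits the prior degrees of freedom were 1013, against 4.69 with all arrays and 3.41 without a control array. The test then took nearly the same spread for every gene, and these calls rest on that shared spread. The median of an array lay near the edge of background, since 50.6% to 51.8% of the spots were well above it. Under median scaling the prior degrees of freedom were 16.45, and each gene named here for its small p passed. That adds no support, since these genes were chosen for their small p on the same 4 arrays.

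Doxycycline array 1 and doxycycline array 2 were the most alike (r = 0.971 across genes, which are not independent replicates), and control array 2 correlated more closely with doxycycline array 2 (r = 0.968) than with control array 1 (r = 0.933). The lowest correlation was between control array 1 and doxycycline array 1 (r = 0.909). The first principal component held 57.8% of the variance. Control array 1 lay at 1 end of it (-75.5) and doxycycline array 1 at the other (52.3). Control array 2 (3.9) and doxycycline array 2 (19.3) lay between. Across gene lists fixed in advance, control array 1 had lower levels of sarcomere and oxidative phosphorylation genes than control array 2, with medians of member differences of -1.23 and -1.12. Not every muscle gene was lower on control array 1. Atrial and conduction muscle markers were 0.60 higher by median, and Myh6 read 10.28 on control array 1 and 9.73 on control array 2. Control array 1 also had higher levels of markers of several other cells, by 1.66 for endothelial, 1.55 for fibroblast, 1.69 for macrophage and 2.24 for red cell markers. Mesothelial (-0.95) and adipocyte (-0.31) markers went the other way. For this reason lists are also given without control array 1 below.

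Genes of fatty acid uptake and oxidation rose as a group after doxycycline. Their median difference was 0.92, 37 of 38 members lay above control on average, and both doxycycline arrays exceeded both control arrays for 28 (camera adjusted p = 2.9e-15 with a preset correlation, adjusted p = 0.726 with an estimated correlation). Largest among the members with the smallest p were Angptl4, a secreted inhibitor of lipoprotein lipase, at 4.603 ± 0.597 (SE, 24.3-fold), and Pdk4, the kinase that turns off pyruvate dehydrogenase, at 4.37 ± 0.65. The acyl-CoA thioesterase gene Acot1 differed by 3.70 ± 0.48 and Ucp3, a mitochondrial carrier induced by fatty acids, by 2.30 ± 0.49. Adjusted over the list alone, 5 members rose and 0 fell, whereas 0 passed over all genes tested. The list's own median on control array 1 was 1.25 below control array 2 by member, and without control array 1 the median difference was 0.29 (adjusted p = 2.4e-06 with a preset correlation). It was 1.55 without control array 2.

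The other metabolic lists moved little. The citric acid cycle genes rose by a median of 0.21 (adjusted p = 0.032 with a preset correlation, adjusted p = 0.852 with an estimated correlation), and 20 of 21 members lay above control, with Pcx at 0.70 ± 0.52 and Dld at 0.97 ± 0.85. Members were lower on control array 1 than on control array 2 by a median of 1.26, and without control array 1 the list was called in the opposite direction with a median of -0.33. The call was also lost without doxycycline array 1 (0.21, adjusted p = 0.097), without doxycycline array 2 (0.33, adjusted p = 0.083) and under median scaling (adjusted p = 0.054) or quantile normalization (adjusted p = 0.068). Nuclear-encoded oxidative phosphorylation genes had a median difference of 0.12 (adjusted p = 0.079), glycolysis and glucose uptake genes of 0.10 (adjusted p = 0.211) and mitochondrial ribosome and translation genes of 0.00 (adjusted p = 0.620). None of the 3 passed in the main analysis. With normexp background correction, the oxidative phosphorylation list (0.30, adjusted p = 1.4e-05) and the glycolysis list (0.235, adjusted p = 0.013) were called higher. With no filter on dim probes all 3 were (0.12, 0.10 and 0.00, adjusted p = 0.00075, 0.0078 and 0.048). Their medians were then the same as in the main analysis, while the median of all genes, with which camera compares a list, moved by -0.249. Without control array 1 the oxidative phosphorylation list stood at -0.42 and the mitochondrial ribosome list at -0.53, both called lower, and without control array 2 they stood at 0.68 and 0.53, both called higher. Glycolysis genes were called higher without control array 2 (0.48, adjusted p = 0.0067) and stood at -0.25 without control array 1 (adjusted p = 0.215). In the ketone body list, the monocarboxylate transporter gene Slc16a6 (1.86 ± 0.49) passed when adjusted over the list alone. Slc16a7 differed by -1.19 ± 0.60, and without control array 1 the 2 genes differed by 1.44 and -0.50. The list of 10 as a whole had a median difference of 0.01 (adjusted p = 0.211). It was called higher without doxycycline array 1 (-0.04, adjusted p = 0.018) and with no filter on dim probes (0.01, adjusted p = 0.024), and did not pass without control array 1 (-0.05, adjusted p = 0.470). That list was fixed with knowledge of the study's interest in ketone metabolism, so it is not independent evidence.

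Sarcomere genes were called higher as a list, with a median difference of 0.55 and 25 of 34 members above control (adjusted p = 0.00014 with a preset correlation, adjusted p = 0.818 with an estimated correlation). Members did not move alike. Both doxycycline arrays exceeded both control arrays for 13 members and lay below both for 5. Among those 5 were Actc1 at -0.87, Myl2 at -0.54, Myl3 at -0.33 and Tpm1 at -0.32. Xirp1, an actin-binding protein of intercalated discs, differed by 2.45 ± 0.50, the Z-disc protein gene Myot by 2.16 ± 0.60, Fbxo32, a ubiquitin ligase of muscle atrophy, by 1.34 ± 0.47 and the intermediate filament gene Des by 1.46 ± 0.54. The list was lower on control array 1 than on control array 2 by a median of 1.23, and without control array 1 its median difference was -0.07 and it did not pass (adjusted p = 0.559). Genes of the fetal heart moved in both directions, with a list median of -0.15, a mean of 0.15 and a test pointing up (adjusted p = 0.496), which passed without doxycycline array 2 (0.41, adjusted p = 0.031). Adjusted over the list alone, Myh7, the slow myosin heavy chain of the fetal mouse ventricle, at 3.24 ± 0.48 (SE, 9.47-fold), and Fhl1 at 2.23 ± 0.53 rose and smooth muscle actin, Acta2, fell by 2.47 ± 0.54. Calcium handling and excitation genes had a median difference of 0.08, with a negative mean of -0.03 (adjusted p = 0.777), and they were called lower without control array 1 (-0.39) and higher without control array 2 (0.53). Medians were 0.00 for cardiac transcription factors (adjusted p = 0.618) and -0.20 for atrial and conduction muscle markers (adjusted p = 0.787). The cardiac transcription factors were called higher without control array 2 (0.54, adjusted p = 0.045). Without control array 1 they stood at -0.35, the fetal list at -0.08 and the atrial list at -0.115, none of which passed.

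Among the stress lists, 3 were called higher with a preset correlation. Immediate early and heat shock genes had a median difference of 0.72, with 23 of 26 members above control (adjusted p = 4.5e-08 with a preset correlation, adjusted p = 0.726 with an estimated correlation). Hmox1, which degrades haem, differed by 2.66 ± 0.51 and was the 1 member that passed when adjusted over the list alone, and Fosl2, Btg2 and Ier3 differed by 1.498, 1.326 and 1.695. The median of this list was 0.86 without control array 1, 0.45 without doxycycline array 1 and 1.21 without doxycycline array 2, and it passed each time. Inflammatory cytokine and acute phase genes had a median difference of 0.76 (adjusted p = 0.00058 with a preset correlation, adjusted p = 0.818 with an estimated correlation), and the iron-binding Lcn2 at 4.69 ± 0.84 and haptoglobin, Hp, at 2.55 ± 0.56 passed when adjusted over the list alone. That group was high on doxycycline array 1 and not on doxycycline array 2, with array medians of -0.25 and -1.87 in control and 2.08 and -1.65 after doxycycline. The list stood at 1.61 without control array 1 and at 2.87 without doxycycline array 2, called higher both times. Without doxycycline array 1 it was called lower (-0.59), and without control array 2 it did not pass (0.17, adjusted p = 0.786). Integrated and endoplasmic reticulum stress genes were mixed. Of 22 members, 15 lay above control, among them Chac1 at 1.89 ± 0.53 and Ppp1r15a at 1.40 ± 0.47. The 7 below control included Sdf2l1 at -1.02 ± 0.49, Pdia4 at -0.88 ± 0.44 and Ddit3 at -0.49 ± 0.42. This list had a median difference of 0.14 (adjusted p = 0.033 with a preset correlation, adjusted p = 0.726 with an estimated correlation). That median was 0.36 without control array 1, where the list passed (adjusted p = 0.024). The call was lost without control array 2 (0.18, adjusted p = 0.311), without doxycycline array 1 (0.09, adjusted p = 0.097) and with quantile normalization (adjusted p = 0.142). Of the p53 targets and cell cycle inhibitors, the inhibitor gene Cdkn1a differed by 3.65 ± 0.54 (12.6-fold) and passed when adjusted over the list alone, while the list did not (median 0.02, adjusted p = 0.184). It was called higher without doxycycline array 2 (0.32, adjusted p = 0.0073), with normexp background correction (0.15, adjusted p = 0.026) and with no filter on dim probes (0.02, adjusted p = 0.0098). Its median was 0.10 without control array 1 (adjusted p = 0.071). Interferon response genes were called lower at -0.35 (adjusted p = 0.027 with a preset correlation, adjusted p = 0.852 with an estimated correlation), with Ifit3 at -1.44 ± 0.48. They were higher on control array 1 than on control array 2 by 1.501, their median without control array 1 was 0.34 with the test pointing up (adjusted p = 0.055), and the call was lost without doxycycline array 2 (-0.27, adjusted p = 0.433) and with no filter on dim probes (-0.54, adjusted p = 0.126).

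**Figure D2:**
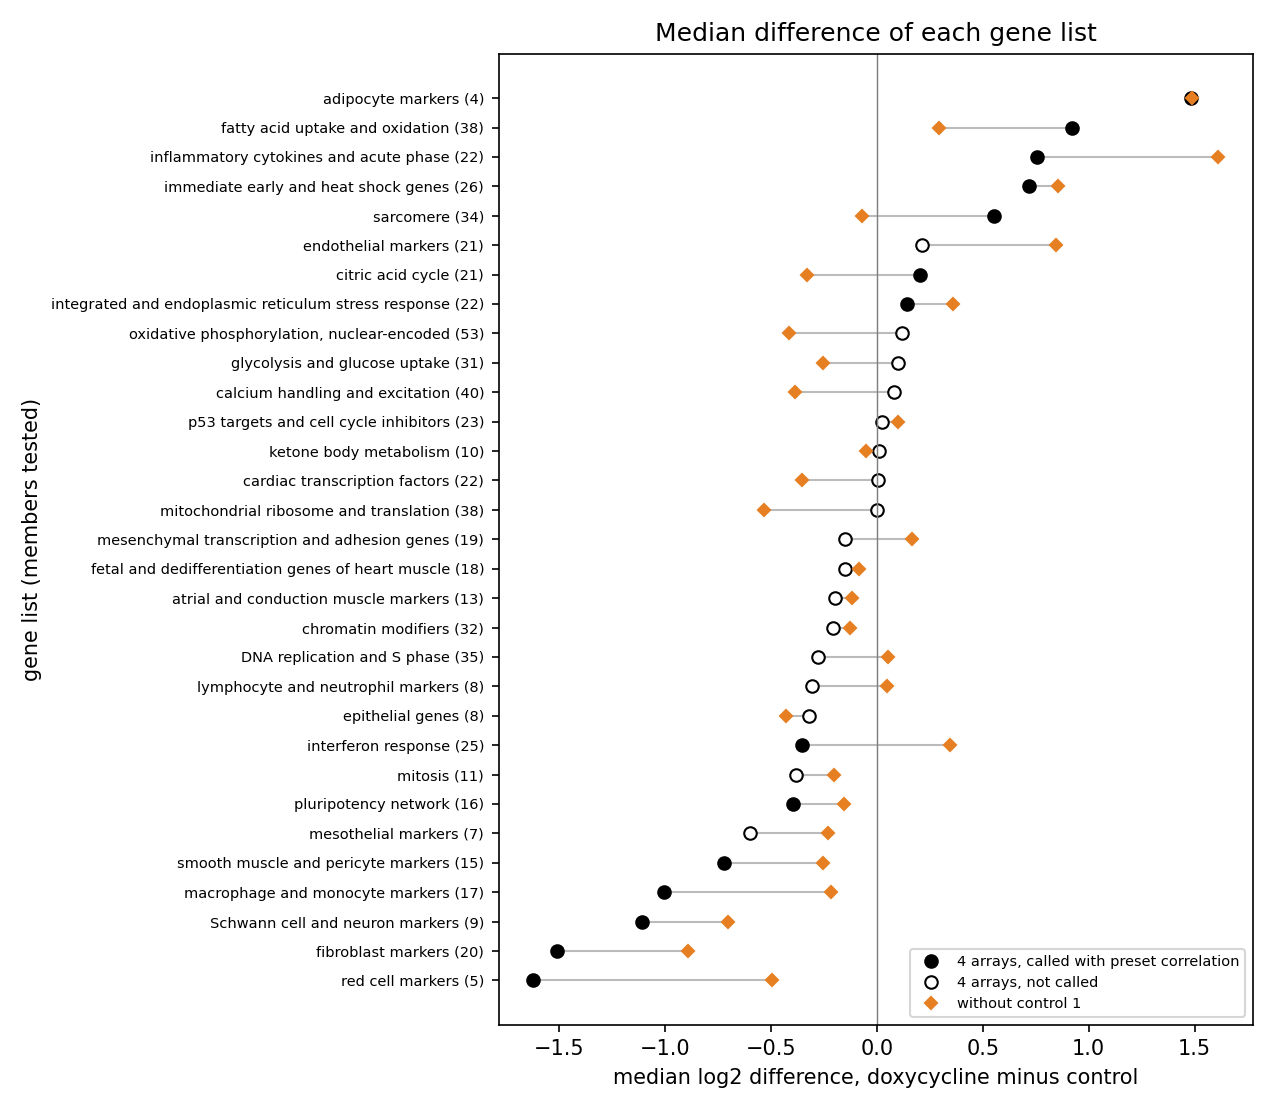
Median log2 difference between doxycycline and control (x axis) of each gene list tested, with the number of members tested in parentheses (y axis). Filled circles are lists called with a preset correlation on 4 arrays, open circles those not called, and orange diamonds the same medians without control array 1, which move the sarcomere list from 0.55 to -0.07 and the fibroblast list from -1.51 to -0.89.

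Fibroblast markers fell after doxycycline, with a median difference of -1.51 and 19 of 20 members below control (adjusted p = 2.3e-09 with a preset correlation, adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone, 9 members fell and 0 rose, among them the collagen genes Col3a1 at -3.59 ± 0.63 and Col1a1 at -2.93 ± 0.65, the proteoglycan gene Lum at -3.76 ± 0.67, and Postn, which was at least 8.79-fold lower. Markers were 1.55 higher on control array 1 than on control array 2 by median, and without control array 1 the difference was -0.89 and passed (adjusted p = 0.018). Schwann cell and neuron markers fell by a median of 1.11, 8 of 9 members lying below control (adjusted p = 9.8e-05 with a preset correlation, adjusted p = 0.726 with an estimated correlation), with Dbh passing when adjusted over the list alone and Gfra3 at -2.39 ± 0.74 and S100b at -2.12 ± 0.73. Their median was -0.70 without control array 1 (adjusted p = 0.036), -1.71 without control array 2 and -0.62 without doxycycline array 1.

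Macrophage and monocyte, red cell, and smooth muscle and pericyte markers also fell, and their calls rested on control array 1. Macrophage and monocyte markers had a median difference of -1.005 (adjusted p = 0.00014 with a preset correlation, adjusted p = 0.818 with an estimated correlation). The chemokine receptor gene Cx3cr1 was at least 4.22-fold lower and was the 1 member that passed when adjusted over the list alone, and Adgre1 and Csf1r differed by -1.61 and -1.43. Red cell markers had a median difference of -1.62 (adjusted p = 0.00091 with a preset correlation, adjusted p = 0.726 with an estimated correlation), with the haemoglobin gene Hba-a1 at -1.62 ± 0.77. Smooth muscle and pericyte markers had a median difference of -0.72 (adjusted p = 0.0032 with a preset correlation, adjusted p = 0.726 with an estimated correlation), and Acta2, which also stands in the fetal list, passed when adjusted over the list alone, while the pericyte markers Kcnj8 and Higd1b differed by -2.01 and -1.97. These 3 lists were higher on control array 1 than on control array 2 by 1.69, 2.24 and 1.32, and without control array 1 their medians were -0.22 (adjusted p = 0.487), -0.49 (adjusted p = 0.064) and -0.25 (adjusted p = 0.461). Endothelial markers differed by a median of 0.21 and did not pass (adjusted p = 0.555). They stood at 0.85 without control array 1 and at -0.60 without control array 2, called in opposite directions.

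Adipocyte markers rose by a median of 1.48 over the 4 members tested (adjusted p = 0.00038 with a preset correlation, adjusted p = 0.726 with an estimated correlation), and Cfd, an adipocyte-secreted complement protease, at 2.18 ± 0.41 and the lipid droplet protein gene Cidea at 2.00 ± 0.55 passed when adjusted over the list alone. The call was lost with another background correction, normexp, where the median was 0.415 (adjusted p = 0.055). With no filter on dim probes the median was 0.28 and the list passed. In the lymphocyte and neutrophil list the median was -0.31, the mean 0.79 and the test pointed up without passing (adjusted p = 0.211), though it passed without doxycycline array 1 (0.02, adjusted p = 0.021) and without doxycycline array 2 (-0.42, adjusted p = 0.0043). The neutrophil genes S100a8, S100a9 and Retnlg differed by 3.67, 3.26 and 2.33 and passed when adjusted over the list alone, whereas another neutrophil gene, Csf3r, differed by -0.33 ± 0.48 and Cd52, of lymphocytes, differed by -1.51 ± 0.59. Mesothelial markers had a median difference of -0.60 (adjusted p = 0.544). The medians of these 3 lists without control array 1 were 1.485, 0.05 and -0.23, and only the adipocyte list passed (adjusted p = 0.0030).

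**Figure D3:**
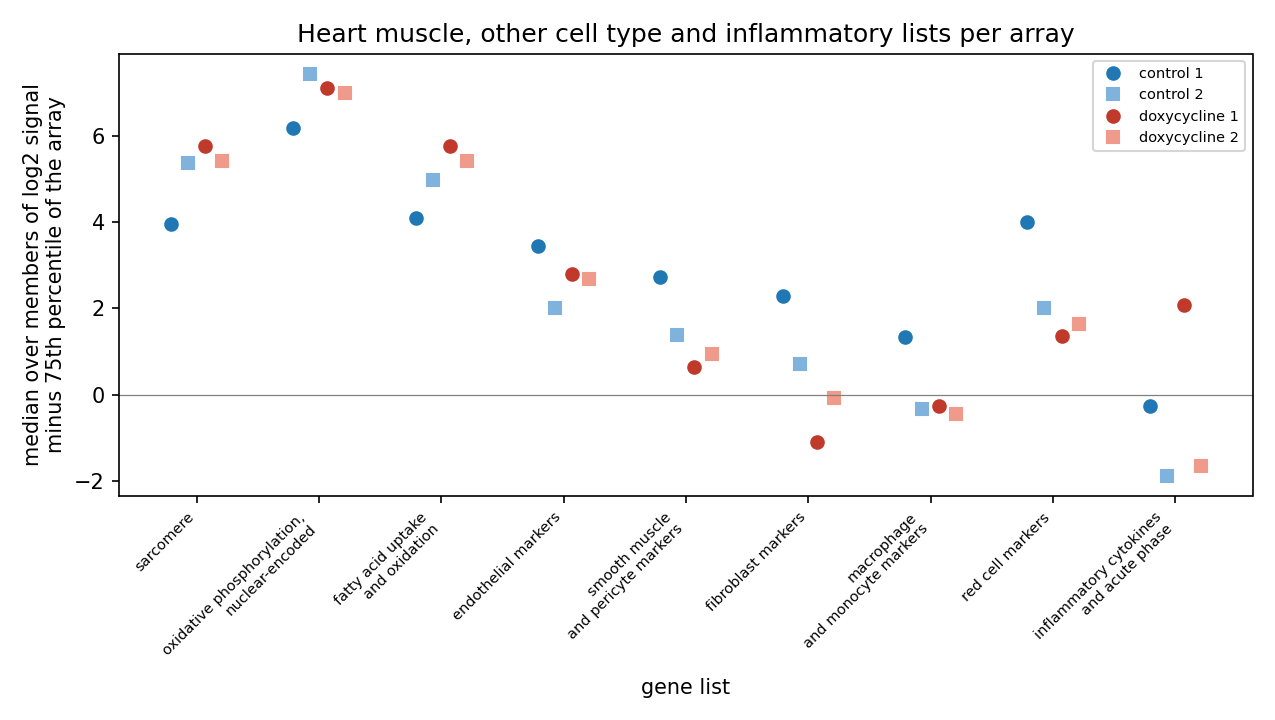
Median level over the members of 9 gene lists (x axis) on each array, as log2 signal minus the 75th percentile of the array (y axis); circles and squares are arrays 1 and 2 of control (blue) and doxycycline (red). Control array 1 lies lowest for the muscle lists, with 3.96 for sarcomere genes, and highest for the other cell types, with 2.30 for fibroblast markers, while the inflammatory list stands at 2.08 on doxycycline array 1 and -1.65 on doxycycline array 2.

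Genes of the pluripotent state did not rise. The pluripotency list fell by a median of 0.39 over 16 members tested (adjusted p = 0.032 with a preset correlation, adjusted p = 0.818 with an estimated correlation), of which 4 lay above control and 12 below. Lefty1, an inhibitor of Nodal signalling, was at least 3.68-fold lower, the Nodal co-receptor gene Tdgf1 differed by -1.77 ± 0.71 and Utf1 by -0.99 ± 0.43. Members were 0.63 higher on control array 1 than on control array 2 by median, and the call was lost without control array 1 (-0.15, adjusted p = 0.559), without doxycycline array 1 (-0.20, adjusted p = 0.097), with quantile normalization (adjusted p = 0.077) and with genes well above background on all 4 arrays (-0.34, adjusted p = 0.273). Mitosis genes, of which 11 were tested, had a median difference of -0.38 (adjusted p = 0.121), with Ube2c at least 2.61-fold lower. They were called lower with normexp background correction (-0.38, adjusted p = 0.024) and with no filter on dim probes (-0.49, adjusted p = 0.0045). DNA replication and S phase genes had a median difference of -0.28 (adjusted p = 0.339), with E2f8 at least 2.27-fold lower and Fen1 at 1.21 ± 0.53. Chromatin modifiers stood at -0.21 (adjusted p = 0.211), epithelial genes at -0.32 (adjusted p = 0.313; called lower with no filter on dim probes, -0.61, adjusted p = 0.019) and mesenchymal transcription and adhesion genes at -0.15 (adjusted p = 0.505), the last called lower without control array 2 (-0.54, adjusted p = 0.045). Grhl2, a transcription factor of epithelia, was at least 2.90-fold lower and passed when adjusted over the epithelial list alone. Snai2, a mesenchymal gene, differed by -1.58 ± 0.68, and by -0.70 without control array 1. Without that array the medians were -0.20 for mitosis, 0.05 for DNA replication, -0.13 for chromatin modifiers, -0.43 for epithelial and 0.17 for mesenchymal genes, none of which passed.

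In all, 7 lists were called higher and 7 lower of 31 tested with a preset correlation of 0.01, and 0 with an estimated correlation or by fry, whose smallest adjusted p was 0.062 for adipocyte markers. The other 2 ways of splitting the 4 arrays into pairs called 18 and 15 lists with the preset correlation. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. Over all genes tested, 0 members of any list passed. Adjusted over the list alone, 0 members passed in each list for which no such member is named. Without control array 1 there were 6 higher and 6 lower, and 7 of the 14 kept their call and direction.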

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

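The tests of fibroblast, fatty acid and clock genes below were chosen after the differences had been seen, except the test on clock genes that had not been looked at, which was set beforehand, as was the comparison of called lists with other splits.

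Probes without a gene name are left out of the comparisons above, and some were well above background in 1 group only: 73 such accessions were well above background on both doxycycline arrays and on neither control array, and 46 the other way round. Among named genes these counts were 119 and 98. When the 3921 unnamed accessions were tested with the named genes by limma, 0 were called (smallest adjusted p = 0.174), and 179 of them had an unadjusted p under 0.05, where chance alone would give about 196.

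Fatty acid uptake and oxidation genes were higher after doxycycline, and the muscle content of control array 1 was weighed as an explanation. Without control array 1 the list's median exceeded that of 87 sarcomere and oxidative phosphorylation genes by 0.665 (interval 0.464 to 0.926), and with all arrays by 0.77. Without control array 1 the medians were 0.29 for fatty acid, -0.07 for sarcomere and -0.42 for oxidative phosphorylation genes. The gap then came in part from oxidative phosphorylation genes lying below control. It argues against a lower share of muscle RNA on that array as the whole cause, though it rests on 1 control array. A fasting or stress hormone state may contribute: 18 glucocorticoid receptor targets had a median difference of 1.22 (interval 0.318 to 2.15), but 11 of them exceeded 0.5, too few to settle it. Doxycycline itself and the factors cannot be told apart, since 0 arrays came from animals given the drug without the factors. The induction of the factors stays among the open explanations, as untested.

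Fibroblast markers were lower, and 3 explanations were set against this. Fewer cells of every other type would move endothelial markers alike, but the fibroblast median lay below the endothelial one by a gap of -1.74 without control array 1 (interval -2.49 to -0.653) and of -1.72 with all arrays. Without control array 1 the gap came in part from endothelial markers, which stood at 0.85. Schwann cell (-0.70), red cell (-0.49), smooth muscle (-0.25), mesothelial (-0.23) and macrophage (-0.22) markers then also lay below control. Lymphocyte and neutrophil (0.05) and adipocyte (1.485) markers did not. Poor quality of control array 1 would end the difference without it. Over 14 matrix genes the median was then -1.39 (interval -1.99 to -0.0419), which argues against that as the whole cause for them. Over the 6 other markers it was -0.0709 (interval -0.941 to 0.565), as that cause would give. Both values rest on 1 control array, and the intervals cover genes and not the spread between arrays. For matrix genes the upper end, -0.0419, was small, so the argument is weak. Whether there were fewer fibroblasts or less matrix transcript per cell stays open as well, since matrix genes differed from the other markers by -1.48 (interval -2.31 to 0.186). An effect of the factors is possible and was not tested.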

How the results depend on the processing

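Array weights and the test of every accession were chosen after seeing the data. Genes higher and lower after doxycycline, 0 and 0 in the main analysis, were 95 and 33 (74.2% higher) under median scaling, which moved the median difference of all genes from -0.06 to 0.29, a shift of 0.35. Relative to the median of all genes, list medians were unaffected by that scaling. With quantile normalization the medians of 6 lists, none of them called, turned in sign, with absolute values up to 0.064. Without a filter on dim probes the median of all genes moved by -0.249. The counts were 394 and 479 at an unadjusted p under 0.05 with an absolute log2 difference of at least 1, and 0 and 0 in the other settings of normalization, filter, probe rule, variance, array weights and accessions, in which 700 to 1871 genes had an unadjusted p under 0.05. Leaving out 1 array gave 0 to 87 higher and 0 to 84 lower, the lone array being assumed to vary like the other group. Fits without a doxycycline array had prior degrees of freedom of 1013, against 4.69 in the main analysis and 3.41 without a control array. Without a doxycycline array, nearly the same spread was thus used for every gene. Why the prior changed was not tested. With the replicate number as a block the counts were 152 and 143, with infinite prior degrees of freedom. Same-numbered arrays did not deviate together (correlation across genes -0.09). With 2 arrays per group, this cannot exclude that the numbers mark a shared animal, litter or day.

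With no filter on dim probes, 7 lists of either direction gained a call and 1 lost it. The oxidative phosphorylation, glycolysis, mitochondrial ribosome, ketone body and p53 lists gained theirs with unchanged medians, while the median of all genes moved by -0.249. Lists called higher, 7 in the main analysis, were 0 with an estimated correlation or fry, as were those called lower (0 against 7). In the other settings 5 to 9 and 6 to 8 were called, and on leaving out 1 array 6 to 10 and 6 to 9. With the block there were 7 and 7, the citric acid cycle losing its call (adjusted p = 0.060) and the lymphocyte and neutrophil list gaining one (adjusted p = 0.0036). On leaving out 1 array, medians ran from -0.3856 to 0.526 for calcium handling, -0.3279 to 0.8851 for citric acid cycle, -0.4159 to 0.6755 for oxidative phosphorylation, -0.5332 to 0.5335 for mitochondrial ribosome and -1.281 to 0.3439 for interferon genes, each turning without control array 1; from -0.5902 to 2.871 for inflammatory genes, turning without doxycycline array 1; and from -0.5963 to 0.8468 for endothelial markers, turning without control array 2. The cause was not tested. Fatty acid, fibroblast, immediate early, and Schwann cell lists were called in 13 of 15 alternatives, all but the estimated correlation and fry. The lowest correlation between arrays, 0.91, was 0.954 with no filter and 0.9095 to 0.9476 on leaving out 1 array. Of 1986 values of 134 named genes under alternatives, 18 changed sign, none of them called. The slide block was not run, since there was 1 slide. Signal over background limits the dim genes, given as bounds.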

Other observations

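The genes in this paragraph were chosen after their values were seen, and none passed the test over all genes. The apelin receptor gene Aplnr was at least 13.6-fold lower after doxycycline, beside its ligand gene Apln at -4.25 in the account above. Fkbp5 and Zbtb16, which glucocorticoids induce, differed by 2.93 ± 0.41 (SE, n = 2 per group) and 2.35 ± 0.41, and Hif3a by 2.29 ± 0.57. Other glucocorticoid targets ranged widely, with Mt2 at 5.24, Mt1 at 2.30, Cebpd and Sult1a1 at 2.02, Ddit4 at 1.56 and Nfkbia at 1.45, and with Sgk1 at 0.46, Tsc22d3 at 0.37, Klf9 at 0.13 and Per1 at 0.11. The kinase gene Map3k6 differed by 3.96 ± 0.52. Saa3, an acute phase gene, read -5.51 and -5.19 on the control arrays, 2.15 on doxycycline array 1 and -3.60 on doxycycline array 2, and Icam1, which recruits leukocytes, likewise read 3.37 on doxycycline array 1 and -1.69 on doxycycline array 2.

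Clock genes were split, and the test on control array 1 was chosen after the result was seen. Arntl differed by 2.41 ± 0.46 and Dbp by -2.86 ± 0.45, which a difference in the time of day of tissue collection could give. The remaining clock genes seen before the test moved less. Tef and Nr1d2 differed by -0.67, Ciart by -0.44, Nr1d1 by -0.40 and Clock by 0.12. Per2, at 0.12, went against the direction such a shift would need. In a test set before their values were seen, 7 other clock genes signed by the direction a shift would need had a median of -0.04 (interval -0.958 to 1.82), and 3 of the 7 moved in that direction, with Nfil3 at 2.32 and Hlf at -1.82 but Por at 0.96. Without control array 1, Arntl and Dbp differed by 1.96 and -2.76, so the smaller of them, 1.96, fell just short of the 2 set as the bound against a cause in that array. Both explanations stay open, the first because the interval is wide.

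The real split of the 4 arrays gave 886 genes at an unadjusted p under 0.05, and the highest of the other splits gave 382, with 1 of the 3 splits as large. The 3 splits are too few for a share under 0.05. Of the gene lists, 14 were called with a preset correlation in the real split, and 18 and 15 in the other splits, so 3 of 3 splits called as many. The number of lists called this way was therefore not particular to the grouping by treatment. Which lists the other splits called was not compared. The gene count was compared with other splits after it was seen.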
